A study of Mus musculus with 15 samples.

How the data were processed

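RNA from 15 mouse samples was measured on MoGene-2_0-st whole-transcript arrays. Per the labels, 8 samples were splenic dendritic cells (DCs), 4 WT and 4 Lkb1 KO, and 7 were regulatory T cells (Tregs) from spleen and peripheral lymph nodes, 4 WT and 3 Lkb1 KO, all of strain C57BL/6. Per the labels' protocols, DCs came from collagenase-digested spleens, were enriched on CD11c beads, and were sorted for CD11c and MHC-II and against TCRβ, CD19 and CD49b. Tregs were enriched on CD4 beads and sorted for CD4 and CD25, per the same protocols. Between 1 and 20 ng of total RNA was amplified and biotin-labelled with NuGEN kits. Lkb1 is the older name of Stk11, and the arrays list the gene as Stk11. The labels do not state in which cells the gene was deleted, whether each sample came from a separate animal, or whether a DC and a Treg sample with the same number shared an animal.

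The deposited values are log2 signal intensities, 1 per transcript cluster and array. Per the submitters' processing notes, they were made with RMA in Affymetrix Expression Console 1.1. RMA corrects background, sets the arrays to 1 distribution and combines probes by median polish. The log2 scale was checked on the values, which ran from 1.69 to 13.36 with nearly equal quantiles in every array. The table held 41345 clusters and 0 missing values, and arrays carry no sequencing depth, so the number of arrays limits the precision. The genome build behind the clusters is not given in the sources used here, so no coordinates are given.

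Clusters were matched to genes through the gene table of the platform. Of the clusters, 23521 had 1 gene symbol, 1820 had several and 16004 were not listed. Where a gene had more than 1 cluster (1082 genes), the cluster with the highest mean over all arrays was used. This left 22180 genes, of which 21994 were found in the RefSeq gene table of assembly GRCm38.p6, used here for gene classes and names alone.

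Each cell type was fitted separately with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), as Lkb1 KO minus WT on the log2 scale. P-values were adjusted by Benjamini-Hochberg over the 22180 genes, with a threshold of 0.05, and intervals are at 95%. The difference between the effects in DCs and in Tregs was tested as an interaction over all 15 arrays. Stk11 was also tested with a 2-sided exact permutation test in each cell type. Overlap between the calls of both cell types was tested with Fisher's exact test, 2-sided. The p-values measure the spread between these samples.

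Gene lists were written before the data were examined. There were 44 lists with 1056 symbols, of which 946 matched a gene tested, and 43 lists had measured members (the 13 mitochondrially encoded genes had none). Lists were tested with camera at a preset correlation between genes of 0.01, adjusted over the 43 lists, with the result at an estimated correlation beside it. They were also tested with fry, which asks whether the members move on balance in 1 direction without comparing them with other genes. Counts of members past the threshold are given over all genes and adjusted over the list alone. The mean log2 level of each list per group was described without a test.

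The genes named followed a rule fixed at the same time as the lists. For each genotype comparison it took Stk11, then the 10 largest rises and 10 largest falls among genes past the threshold whose KO and WT arrays did not overlap. It further took up to 4 members per list with the largest change past the threshold, or up to 2 with the smallest p where none passed. For the interaction it took the 5 largest values in each direction, and for the overlap up to 6 genes by the smaller of both changes. Predicted genes, clone names, microRNAs, olfactory and vomeronasal receptors and antigen receptor segments were counted but not named by rank.

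The method was tested on simulated data with 22180 genes per cell type. Each gene was drawn independently around its real mean over the arrays of a cell type, with its real spread within groups. In DC data 90% of 100 genes changed by 1 on the log2 scale were recovered, and 32% of 100 genes changed by 0.5. In Treg data 92% and 50% were recovered, respectively. False calls were 8 of 130 in DC data and 8 of 150 in Treg data. A list shifted as a whole was called in both, with 0 of the other lists. Because genes were drawn independently, this does not test lists whose members correlate. In the real Treg data the cell cycle list had an estimated correlation of 0.80.

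Alternatives, planned at that time too, were quantile normalization of the arrays again, centring of each array on its median, dim genes left out, every cluster in place of 1 per gene, and the mean of all clusters of a gene. Others were array weights, a trended and robust eBayes, all 15 arrays in 1 model, a required 2-fold change, a replicate block, and each array left out in turn. After the data were seen, the fit without WT Treg 1 and Lkb1 KO Treg 1 together, a fit on protein-coding genes alone, and an interaction fit with a block shared by DC and Treg arrays of the same genotype and number were added. Calls were compared with those from other splits of the arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No array was left out of the results given in the report; clusters with several or no gene symbols were.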

Results

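RNA levels were measured on arrays in 2 sorted immune populations labelled WT or Lkb1 KO. The groups were 4 WT and 4 Lkb1 KO samples of splenic DCs, and 4 WT and 3 samples of Tregs labelled Lkb1 KO. The series title places the study in the field of LKB1, DC metabolic quiescence and anti-tumour immunity. Each comparison asks which genes differ with the Lkb1 genotype of the label. The median signal over all clusters was 4.70 to 4.88 per array on the log2 scale, and replicates of a group correlated across clusters with Pearson r of 0.984 to 0.992. Clusters are not independent replicates.

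Markers of the sorted populations matched the label of cell type in each group. The 15 measured T cell markers averaged 9.86 ± 0.04 (SD, n = 4) on the log2 scale in WT Tregs and 4.91 ± 0.10 (SD, n = 4) in WT DCs. The 24 genes of the Treg core signature averaged 9.10 ± 0.06 in WT Tregs and 5.84 ± 0.05 in WT DCs. The 23 markers of conventional type 1 DCs (cDC1s) averaged 5.90 ± 0.22 in WT Tregs and 8.94 ± 0.20 in WT DCs. Sort, tissue and cell type differ together here, so no test was made.

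Stk11, the gene encoding LKB1, was lower in knockout DCs but not in the Treg arrays labelled Lkb1 KO. In DCs its mean was 8.09 ± 0.04 (SD, n = 4) in WT and 7.24 ± 0.15 (SD, n = 4) in knockout arrays. The difference was −0.85 (SE 0.09, 95% interval −1.05 to −0.65; limma adjusted p = 9.55e-05), with all 4 knockout arrays below all 4 WT arrays. The exact permutation p was 0.0286, the smallest that these arrays can give. In Tregs the mean was 7.96 ± 0.07 (SD, n = 4) in WT arrays and 8.16 ± 0.05 (SD, n = 3) in arrays labelled Lkb1 KO. That difference of 0.19 (SE 0.08, 95% interval 0.02 to 0.36) did not pass the threshold (limma adjusted p = 0.129; exact permutation p = 0.0286, the smallest possible), although all 3 arrays labelled Lkb1 KO were above all 4 WT arrays. It passed, at 0.33 with a limma adjusted p = 0.0130, when each array was centred on its median. The DC effect minus the Treg effect was −1.05 (SE 0.12, interaction adjusted p = 2.04e-05).

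**Figure D1:**
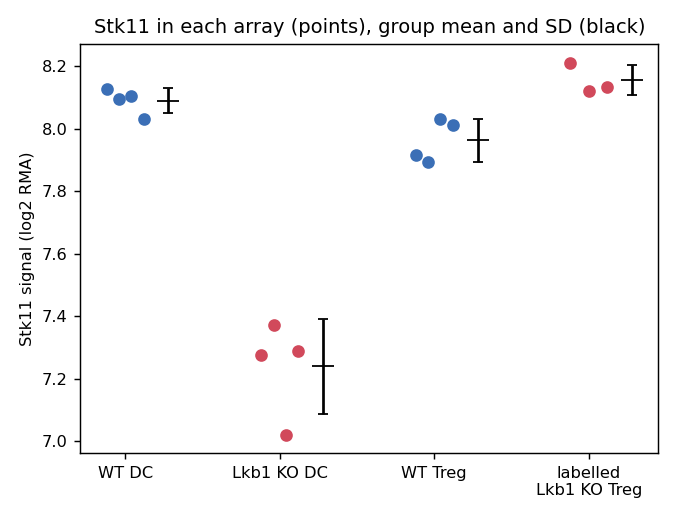
Stk11 log2 signal in each array (points) of the 4 groups, with the group mean and SD in black. Knockout DC arrays lie between 7.02 and 7.37, below the WT DC arrays at 8.03 to 8.13, whereas Treg arrays labelled Lkb1 KO lie between 8.12 and 8.21, above the WT Treg arrays at 7.90 to 8.03.

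In splenic DCs, 1445 of 22180 genes differed between knockout and WT, 820 higher and 625 lower. Among called genes whose knockout and WT arrays did not overlap, the largest rise was in Mmp25, a membrane-anchored matrix metalloproteinase, from 6.11 ± 0.14 (SD, n = 4) in WT to 10.08 ± 0.26 (SD, n = 4) in knockout DCs, a 15.6-fold difference (adjusted p = 5.08e-09). Ramp3, a subunit of calcitonin-family receptors, rose by 3.24 (SE 0.13) and Il1r2, the decoy receptor for interleukin-1, by 3.18 (SE 0.08). Scin, which encodes an actin-severing protein, rose by 3.17 (SE 0.20), and Nr4a2, an orphan nuclear receptor, by 2.92 (SE 0.14). Flrt3, Nrp2, Timd4, the chemokine gene Ccl22 and the endocytic adaptor gene Dab2 rose by 2.76, 2.73, 2.69, 2.63 and 2.60.

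The largest falls in knockout DCs, among genes whose arrays did not overlap, included genes known from macrophages. Mrc1, the mannose receptor, went from 8.29 ± 0.11 (SD, n = 4) in WT to 5.96 ± 0.17 (SD, n = 4), a change of −2.33 (SE 0.10; adjusted p = 9.19e-08). The macrophage elastase gene Mmp12 changed by −2.09 (SE 0.22), the iron exporter gene Slc40a1 by −2.08 (SE 0.11) and Cd5l by −2.03 (SE 0.10). Scel changed by −2.26, Cyp4f37 by −2.09, the chemokine receptor gene Ccr3 by −2.01, the prostaglandin D synthase gene Hpgds by −1.86, the chemokine gene Ccl3 by −1.85 and the sodium channel gene Scn3a by −1.83.

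**Figure D2:**
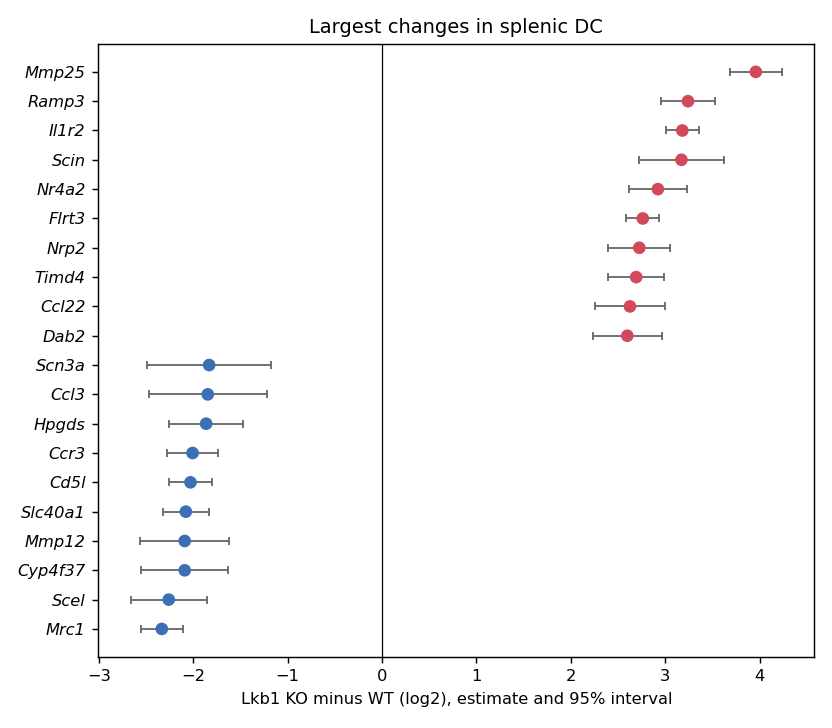
Difference between knockout and WT DCs (log2, points) with its 95% interval (bars) for the 10 largest rises and 10 largest falls named by the rule. Mmp25 has the highest value at 3.96 and Mrc1 the lowest at −2.33.

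Genes of DC maturation rose together in knockout DCs. Of the 36 measured members, 28 rose and 0 fell, and 31 rose when adjusted over the list alone (camera adjusted p = 5.11e-37; adjusted p = 0.0723 with an estimated correlation). Ccl22, the tetraspanin gene Cd63 (2.39, SE 0.09), the actin-bundling gene Fscn1 (2.25, SE 0.12) and Cd200 (2.06, SE 0.12) had the largest rises. The list of tolerogenic and Treg-inducing DC molecules shares Ccl22, Ccl17, Cd80, Cd86, Cd274 and Pdcd1lg2 with the maturation list. It had 6 rises and 1 fall among 26 members, or 10 and 2 adjusted over the list alone (camera adjusted p = 4.97e-04; adjusted p = 0.120 with an estimated correlation). Besides Ccl22 these included Pvr (1.29), Tnfsf4 (1.23) and Cd274, which encodes PD-L1 (0.66). The chemokine receptor gene Ccr7, a member of both the DC maturation and the resting T cell list, rose by 1.72 (SE 0.12). In the same arrays 18 of 28 monocyte and macrophage markers fell and 1 rose, and 9 of 22 granulocyte markers rose and 1 fell.

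Markers of conventional DC subsets passed the camera test in opposite directions, but not the fry test. Of 23 cDC1 markers, 4 rose and 0 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.00183; adjusted p = 0.617 with an estimated correlation), among them Ly75 (1.01) and Gcsam (0.88). The other risers were Cd226 and Id2. The Cd226 call ended under 6 of the alternatives, 5 of which left out 1 array, and the Id2 call under 4, 3 of which did. Of 27 markers of conventional type 2 DCs (cDC2s), 1 rose and 7 fell, or 1 and 12 adjusted over the list alone (camera adjusted p = 1.22e-05; adjusted p = 0.283 with an estimated correlation). Il1r2 was the member that rose, whereas Mmp12, Cd4 (−1.48) and Dtx1 (−1.25) fell. With fry the adjusted p was 0.248 for cDC1 and 0.247 for cDC2 markers, and the camera call for cDC1 markers ended when WT DC 2 was left out (adjusted p = 0.103). Of 20 markers of plasmacytoid DCs 3 rose and 1 fell, or 5 and 3 adjusted over the list alone. That list did not pass the camera test (adjusted p = 0.110) but passed the fry test upward (adjusted p = 0.00749). Atp1b1 rose by 1.84 and Klra17 by 1.55.

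Antigen presentation genes also moved in both directions. Among 18 MHC class II presentation genes 0 rose and 3 fell, or 0 and 5 adjusted over the list alone (camera adjusted p = 3.28e-04; adjusted p = 0.283 with an estimated correlation). H2-Ob (−0.70) and H2-Oa (−0.67), which encode the subunits of H2-O, and H2-DMa (−0.41), which encodes a subunit of H2-M, were these 3; they regulate peptide loading. The H2-DMa call ended with all 15 arrays in 1 model. In the same arrays 5 of 18 B cell markers and 18 of 28 macrophage markers, from cell types that also express class II, fell, and 1 of each list rose. The DC sort was against the B cell marker CD19. For MHC class I presentation 2 of 17 genes rose and 0 fell, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.00387; adjusted p = 0.283 with an estimated correlation). They were Nlrc5 (0.71), a transactivator of class I genes, and Tapbpl (0.53). Interferon gamma response genes had 5 rises and 0 falls among 20, or 8 and 0 adjusted over the list alone (camera adjusted p = 0.00198; adjusted p = 0.265 with an estimated correlation), with Gbp5 (1.20) and Irf1 (0.72) among them.

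Markers of other cell types differed between knockout and WT DCs as well. Of 28 monocyte and macrophage markers 1 rose and 18 fell, or 1 and 21 adjusted over the list alone (camera adjusted p = 5.75e-19; adjusted p = 0.0998 with an estimated correlation). Timd4 was the member that rose, and Adgre1, which encodes F4/80, changed by −1.74 (SE 0.18) beside Slc40a1 and Cd5l. The mean of that list was 7.98 ± 0.10 (SD, n = 4) in WT and 7.29 ± 0.10 (SD, n = 4) in knockout DCs. Of 22 granulocyte markers 9 rose and 1 fell, or 11 and 1 adjusted over the list alone (camera adjusted p = 3.42e-07; adjusted p = 0.265 with an estimated correlation). Il1r2, Ltf (1.48, SE 0.22) and Ngp (1.46, SE 0.27) rose and Mmp9 fell by 1.29, and the mean of the list was 5.66 ± 0.16 in WT and 6.23 ± 0.17 in knockout DCs. Of 18 B cell markers 1 rose and 5 fell, or 2 and 6 adjusted over the list alone (camera adjusted p = 0.0323; adjusted p = 0.269 with an estimated correlation). Cr2 (−1.39), Fcrl1 (−1.16) and Cd22 (−1.16) fell and Blk (1.00) rose. The B cell call ended with dim genes left out (adjusted p = 0.121), with the mean of all clusters of a gene (adjusted p = 0.107), and without WT DC 2 (0.0545), Lkb1 KO DC 2 (0.0957) or Lkb1 KO DC 4 (0.0735).

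Cell cycle genes passed the camera test upward in knockout DCs, but not the fry test (adjusted p = 0.0515). Over all genes 8 of 38 members rose and 0 fell, and 31 rose adjusted over the list alone (camera adjusted p = 7.42e-16; adjusted p = 0.283 with an estimated correlation). Uhrf1 rose by 0.81 (SE 0.13), Bub1 by 0.59 and Aurkb by 0.58. Calls of Bub1 and Aurkb each ended under 5 of the alternatives, 3 of which left out 1 array. Birc5 rose too, but its call ended under 10 alternatives, 6 of which left out 1 array. In the same arrays 9 of 22 granulocyte markers rose and 1 fell.

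Lists of energy metabolism did not pass in knockout DCs, whereas amino acid response genes and LXR targets did. Of 53 oxidative phosphorylation genes 0 passed the limma threshold, over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05 (camera adjusted p = 0.344). Of 19 tricarboxylic acid cycle genes 0 passed on either count and 2 had an unadjusted p under 0.05 (camera adjusted p = 0.610). Of 21 glycolysis genes 4 rose and 1 fell, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.140). The regulatory enzyme gene Pfkfb3 rose by 0.92 (SE 0.15) and the glucose transporter gene Slc2a3 fell by 1.02. Amino acid response and one-carbon genes had 1 rise and 0 falls among 22, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.00974; adjusted p = 0.283 with an estimated correlation), and the rise was in the cystine transporter gene Slc7a11 (1.80, SE 0.13). Of 9 cholesterol efflux and LXR targets 0 rose and 2 fell, Apoe (−0.92) and Abca1 (−0.65), or 0 and 4 adjusted over the list alone (camera adjusted p = 0.0323; adjusted p = 0.283 with an estimated correlation). The amino acid call ended without WT DC 2 (adjusted p = 0.0674), and the LXR call ended without WT DC 2 (0.110), without Lkb1 KO DC 2 (0.0531) and with dim genes left out (0.0812). In the same arrays 18 of 28 monocyte and macrophage markers fell and 1 rose.

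CREB and CRTC targets passed the camera test in knockout DCs, whereas the list of the LKB1 complex and AMPK-related kinases did not. Of 18 CREB and CRTC targets 6 rose and 2 fell, or 8 and 2 adjusted over the list alone (camera adjusted p = 2.69e-04; adjusted p = 0.119 with an estimated correlation). Nr4a2, Nr4a3 (1.22), Gem (0.94) and Crem (0.68) had the largest changes. Of 21 genes of the LKB1 complex and the AMPK-related kinases 3 rose and 1 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.120, fry adjusted p = 0.00553 upward). Nuak2 (1.18), Sik3 (0.79) and Sik1 (0.66) rose, and the fall was in Stk11 itself. Of 30 inflammatory cytokines and NF-kB targets 10 rose and 4 fell, or 12 and 6 adjusted over the list alone (camera adjusted p = 0.0246; adjusted p = 0.283 with an estimated correlation). Gadd45b (1.03) rose, whereas Ccl3 and Tnf (−1.23, SE 0.12) fell. That call ended without WT DC 1 (adjusted p = 0.0508) or Lkb1 KO DC 2 (0.0531). Of 24 Treg core signature genes, written for T cells, 8 rose and 1 fell in DCs, or 9 and 1 adjusted over the list alone (camera adjusted p = 5.03e-05; adjusted p = 0.265 with an estimated correlation). Socs2 (1.68), the interleukin receptor gene Il2ra (1.53) and Tnfrsf4 (1.27) were among them. Socs2 and Cd83 of this list also stand in the DC maturation list. The mean of the 15 T cell markers was 4.91 in WT and 5.11 in knockout DCs. Among DC arrays, T cell markers and Treg core genes both had their highest mean in Lkb1 KO DC 2.

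Another 22 lists did not pass the camera test in DCs (adjusted p from 0.0611 to 0.994). With each array centred on its median, T cell and plasma cell markers passed (0.0369 and 0.0452). The rises and falls follow, with numbers adjusted over the list alone in parentheses. T cell receptor response genes had 7 and 6 of 19 (7 and 6), resting T cell genes 5 and 3 of 19 (5 and 4), effector Treg genes 4 and 1 of 33 (6 and 2) and T helper lineage genes 3 and 1 of 22 (5 and 1). Lysosome and TFE/MITF targets had 0 and 6 of 34 (2 and 8), with Ctsd at −0.96, NRF2 targets 3 and 2 of 14 (3 and 2), p53 targets 3 and 2 of 16 (3 and 2), with Cdkn1a at 1.45, and hypoxia targets outside glycolysis 2 and 0 of 14 (2 and 2). Immediate early and dissociation stress genes had 2 and 4 of 22 (3 and 5), with Egr1 at −0.97, and type I interferon response genes 1 and 1 of 32 (2 and 1). Fatty acid oxidation had 2 and 1 of 23 (2 and 1), sterol biosynthesis 2 and 0 of 20 (4 and 0), fatty acid synthesis 1 and 0 of 16 (1 and 0), ribosome biogenesis 1 and 0 of 25 (1 and 0) and ribosomal proteins 0 and 1 of 35 (0 and 0). T cell markers had 1 and 0 of 15 (1 and 0), CD8 T cell markers 0 and 0 of 12 (0 and 0), plasma cell markers 1 and 0 of 11 (2 and 0) and NK cell markers 1 and 0 of 15 (1 and 0). Erythroid markers had 0 and 0 of 12 (0 and 0), megakaryocyte markers 0 and 1 of 11 (0 and 1) and stromal and endothelial markers 1 and 1 of 16 (1 and 1). Median, mean and test differed in sign for 10 of the lists that did not pass: immediate early, hypoxia, tricarboxylic acid cycle, p53, resting T cell, T helper, T cell receptor response, NK, megakaryocyte, and stromal.

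Knockout and WT arrays did not overlap in 2820 of all 22180 genes (12.7%), which chance gives for 2.86% of genes. Of the 1445 genes called, 242 differed at least 2-fold. The camera test called 16 of 43 lists in DCs, 11 upward and 5 downward, but with an estimated correlation 0 passed (7 had an unadjusted p under 0.05), while fry kept 13 of the 16. Fry also called upward the LKB1 complex and AMPK-related kinases (adjusted p = 0.00553), plasmacytoid DC markers (0.00749) and T cell receptor response genes (0.00320).

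In Tregs, 3155 of 22180 genes differed between the arrays labelled Lkb1 KO and WT, 2274 higher and 881 lower, although Stk11 was not lower. Among called genes whose groups did not overlap, Atp6v0d2, a subunit of the vacuolar proton pump, had the largest rise, from 4.58 ± 0.25 (SD, n = 4) in WT to 7.50 ± 0.20 (SD, n = 3), a 7.54-fold difference (adjusted p = 1.59e-05). Il1r2 rose by 2.53 (SE 0.15), and Chil3, Ngp, Ltf, Lcn2 and Camp, genes known from granulocytes and other myeloid cells, by 2.36, 2.22, 2.07, 1.68 and 1.67. The histone gene H1f5 rose by 1.84 (SE 0.34), Apol9b by 1.73 (SE 0.16) and Anxa1 by 1.66 (SE 0.26). The largest falls were in Gpr52 (−1.65, SE 0.16), Phxr4 (−1.49), Morf4l1-ps1 (−1.23), Arhgap20 (−1.21) and Tbrg3 (−1.13). Pou5f2 (−1.12), Insyn2b (−1.12), the long non-coding RNA Kcnq1ot1 (−1.11), the transcription factor gene Bach2 (−1.05, SE 0.10) and Slc35d1 (−1.02) followed. Long non-coding RNA genes were more often lower (105 of 1921) than higher (13) in these arrays. Clusters outside the gene table were too (2196 of 16004 lower, 414 higher). Whether the falls named here belong to that wider pattern was not tested. Slc40a1 passed too, at 1.77, but its arrays overlapped. Calls of Chil3, H1f5 and Camp ended with a trended and robust eBayes (adjusted p = 0.0530, 0.0532 and 0.0810), and that of Camp also without Lkb1 KO Treg 2 (0.0623) or Lkb1 KO Treg 3 (0.0645).

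**Figure D3:**
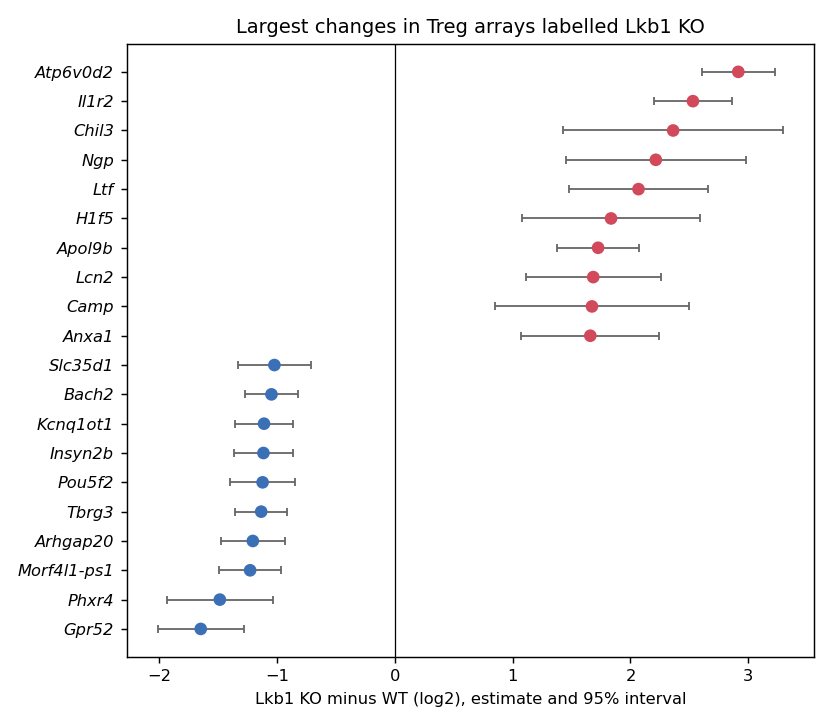
Difference between Treg arrays labelled Lkb1 KO and WT (log2, points) with its 95% interval (bars) for the 10 largest rises and 10 largest falls named by the rule. Atp6v0d2 has the highest value at 2.92 and Gpr52 the lowest at −1.65, and Stk11 was not lower in these arrays.

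Granulocyte markers rose in the Treg arrays labelled Lkb1 KO, in which Stk11 was not lower. Of 22 members 17 rose and 0 fell, or 19 and 0 adjusted over the list alone (camera adjusted p = 2.78e-14; adjusted p = 0.230 with an estimated correlation). The mean of the list was 5.39 ± 0.18 (SD, n = 4) in WT and 6.60 ± 0.43 (SD, n = 3) in these arrays. Of 28 monocyte and macrophage markers 3 rose and 0 fell, or 2 and 0 adjusted over the list alone (camera adjusted p = 1.98e-05; adjusted p = 0.348 with an estimated correlation), among them Axl (from 7.54 to 8.64, SE of the change 0.13) and Ccr2 (0.82). Their mean was 5.96 ± 0.30 in WT and 6.56 ± 0.41 in arrays labelled Lkb1 KO. Over all genes 2274 of 22180 rose, a share near that of 3 of 28. Of 27 cDC2 markers 10 rose and 0 fell, or 13 and 0 adjusted over the list alone (camera adjusted p = 2.36e-05; adjusted p = 0.0883 with an estimated correlation), with Itgam at 1.25 (SE 0.22) and Ccr6 at 0.88. Of 11 plasma cell markers 5 rose and 0 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.0163; adjusted p = 0.299 with an estimated correlation). Irf4 (0.80), which activated T cells also express, was the largest. Irf4, Ccr6 and Ccr2 stand in the effector Treg list too. The plasma cell call ended with dim genes left out (adjusted p = 0.142) and without Lkb1 KO Treg 1 (0.0641).

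Every measured cell cycle gene rose in the Treg arrays labelled Lkb1 KO, in which Stk11 was not lower. All 38 members passed, with 38 and 0 adjusted over the list alone too (camera adjusted p = 1.03e-25; adjusted p = 0.245 with an estimated correlation). Birc5 rose by 1.35 (SE 0.22), Bub1 by 1.22, Kif20a by 1.20 and the mitotic kinase gene Cdk1 by 1.19. The mean of the list was 7.28 ± 0.30 (SD, n = 4) in WT and 8.16 ± 0.08 (SD, n = 3) in these arrays. Among WT arrays WT Treg 1 was highest for the mean of this list (7.63) and for that of macrophage markers (6.37), which lay above Lkb1 KO Treg 2 (6.19). Of granulocyte markers 17 of 22 rose in the arrays labelled Lkb1 KO.

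The effector Treg list passed upward and the resting T cell list downward in the same arrays. Of 33 effector Treg genes 24 rose and 0 fell, or 30 and 0 adjusted over the list alone (camera adjusted p = 1.15e-17; adjusted p = 0.212 with an estimated correlation). The chemokine receptor gene Ccr4 rose by 1.62 (SE 0.11), the integrin gene Itgae by 1.41 (SE 0.18), Glrx by 1.29 (SE 0.11) and Havcr2, which encodes TIM-3, by 1.26 (SE 0.15). Of 19 resting T cell genes 1 rose and 5 fell, or 1 and 9 adjusted over the list alone (camera adjusted p = 1.83e-04; adjusted p = 0.299 with an estimated correlation). Bach2, Foxp1 (−0.68) and Satb1 (−0.65) fell. Havcr2 averaged 5.67 in WT Tregs and 10.66 in WT DCs. In the arrays labelled Lkb1 KO 17 of 22 granulocyte, 10 of 27 cDC2 and 3 of 28 macrophage markers rose as well, beside 2274 of all 22180 genes. Among the markers that rose, Ccr6 and Irf4 (cDC2) and Ccr2 (macrophage) are also effector Treg genes. Il1r2 counts in both the granulocyte and the cDC2 list. Of 24 Treg core signature genes 6 rose and 0 fell, with the same numbers adjusted over the list alone (camera adjusted p = 0.00603; adjusted p = 0.179 with an estimated correlation), among them Tigit (0.97), Penk (0.84) and Socs2 (0.79). The core signature call ended with quantile normalization again (adjusted p = 0.311) and with dim genes left out (0.242).

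In the Treg arrays labelled Lkb1 KO, in which Stk11 was not lower, 7 lists of metabolism and lysosome genes passed the camera test upward. Fatty acid synthesis and LXR targets did not pass that test. Of 53 oxidative phosphorylation genes 26 rose and 0 fell, or 29 and 0 adjusted over the list alone (camera adjusted p = 3.30e-10; adjusted p = 0.179 with an estimated correlation), with Uqcrc1 at 0.59 and Ndufa8 at 0.56. Of 19 tricarboxylic acid cycle genes 9 rose and 0 fell, or 13 and 0 adjusted over the list alone (camera adjusted p = 4.16e-07; adjusted p = 0.0860 with an estimated correlation), with Idh3a at 0.85 (SE 0.08). Glycolysis had 13 rises and 1 fall among 21, or 15 and 2 adjusted over the list alone (camera adjusted p = 5.51e-06; adjusted p = 0.120 with an estimated correlation), with Tpi1 at 0.83 (SE 0.13) and Pgk1 at 0.60. Fatty acid oxidation had 10 rises and 0 falls among 23, or 14 and 0 adjusted over the list alone (camera adjusted p = 4.38e-05; adjusted p = 0.179 with an estimated correlation), with Hadh at 0.72 (SE 0.08). Amino acid response and one-carbon genes had 11 rises and 0 falls among 22, or 14 and 0 adjusted over the list alone (camera adjusted p = 1.03e-05; adjusted p = 0.0883 with an estimated correlation), with Sesn2 at 0.77 and the serine synthesis genes Psat1 at 0.75 and Phgdh at 0.71. Sterol biosynthesis had 8 rises and 0 falls among 20, or 10 and 0 adjusted over the list alone (camera adjusted p = 1.74e-04; adjusted p = 0.299 with an estimated correlation), with Tmem97 at 0.75. Lysosome and TFE/MITF targets had 13 rises and 1 fall among 34, or 24 and 2 adjusted over the list alone (camera adjusted p = 7.02e-08; adjusted p = 0.179 with an estimated correlation), with Atp6v0d2 and Atp6v1a (0.60, SE 0.08). In the same arrays all 38 cell cycle genes, 17 of 22 granulocyte markers and 3 of 28 macrophage markers rose, beside 2274 of all 22180 genes.

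A further 6 lists passed the camera test upward in Tregs, again in arrays in which Stk11 was not lower. Like the other lists called, they did not pass with an estimated correlation. Fry kept all of them but the interferon gamma and MHC class II lists. DC maturation genes had 9 rises and 1 fall of 36, or 12 and 2 adjusted over the list alone (camera adjusted p = 0.00721; adjusted p = 0.179 with an estimated correlation), with the costimulatory gene Cd80 at 1.07 (mean 7.19 in WT Tregs and 9.56 in WT DCs). Interferon gamma response genes had 6 and 0 of 20, or 11 and 1 adjusted over the list alone (camera adjusted p = 0.00644; adjusted p = 0.361 with an estimated correlation), with Icam1 at 0.54. MHC class I presentation had 5 and 0 of 17, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.00106; adjusted p = 0.299 with an estimated correlation). MHC class II presentation had 5 and 1 of 18, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.0278; adjusted p = 0.363 with an estimated correlation), with H2-Oa at 1.02 (mean 7.09 in WT Tregs and 10.70 in WT DCs). In the same arrays 10 of 27 cDC2 and 3 of 28 macrophage markers rose, beside 2274 of all 22180 genes. Ribosome biogenesis and MYC targets had 6 and 0 of 25, or 8 and 0 adjusted over the list alone (camera adjusted p = 0.00164; adjusted p = 0.338 with an estimated correlation), with Pes1 at 0.48. NRF2 targets had 5 and 1 of 14, with the same numbers adjusted over the list alone (camera adjusted p = 0.0154; adjusted p = 0.307 with an estimated correlation), with Txn1 at 0.68. All 6 calls ended with quantile normalization again (adjusted p = 0.0895, 0.106, 0.106, 0.150, 0.177 and 0.177, in the order given) and with dim genes left out (0.261, 0.142, 0.0690, 0.170, 0.142 and 0.306). The class II call also ended with each array centred on its median (0.107), without WT Treg 3 (0.114) and without Lkb1 KO Treg 1 (0.0829), the NRF2 call without Lkb1 KO Treg 1 (0.0590), and the interferon gamma call without Lkb1 KO Treg 2 (0.0997).

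The 22 lists that did not pass the camera test in Tregs (lowest camera adjusted p 0.0558) are given by their rises and falls, with numbers adjusted over the list alone in parentheses. Of genes tied to signalling, the LKB1 complex and AMPK-related kinases had 3 and 0 of 21 (3 and 0), CREB and CRTC targets 1 and 1 of 18 (1 and 1), T cell receptor response genes 2 and 0 of 19 (2 and 0) and T helper lineage genes 1 and 1 of 22 (1 and 1). Tolerogenic and Treg-inducing molecules had 6 and 0 of 26 (7 and 1), with the cytokine subunit gene Ebi3 at 1.26, and inflammatory cytokines and NF-kB targets 5 and 2 of 30 (6 and 2), with Il1b at 1.22 (SE 0.18). Type I interferon response had 3 and 1 of 32 (3 and 2), immediate early and dissociation stress 1 and 0 of 22 (0 and 0), hypoxia targets outside glycolysis 3 and 0 of 14 (3 and 0), with Ddit4 at 0.85, and p53 targets 4 and 1 of 16 (6 and 1). Fatty acid synthesis had 4 and 0 of 16 (4 and 0), cholesterol efflux and LXR targets 3 and 0 of 9 (3 and 0) and ribosomal proteins 1 and 0 of 35 (1 and 0). Among cell type markers, cDC1 had 4 and 0 of 23 (4 and 0), plasmacytoid DC 3 and 2 of 20 (3 and 2), T cell 1 and 0 of 15 (4 and 2), CD8 T cell 3 and 0 of 12 (3 and 0), with Cd8a at 0.92, and B cell 3 and 0 of 18 (3 and 0), with Cd79b at 1.03. NK cell markers had 1 and 1 of 15 (1 and 1), with Gzmb at 1.04, erythroid 0 and 0 of 12 (0 and 0), megakaryocyte 0 and 0 of 11 (0 and 0) and stromal and endothelial 0 and 1 of 16 (0 and 1). Median, mean and test differed in sign for 3 of these: CREB and CRTC, B cell and megakaryocyte.

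**Figure D4:**
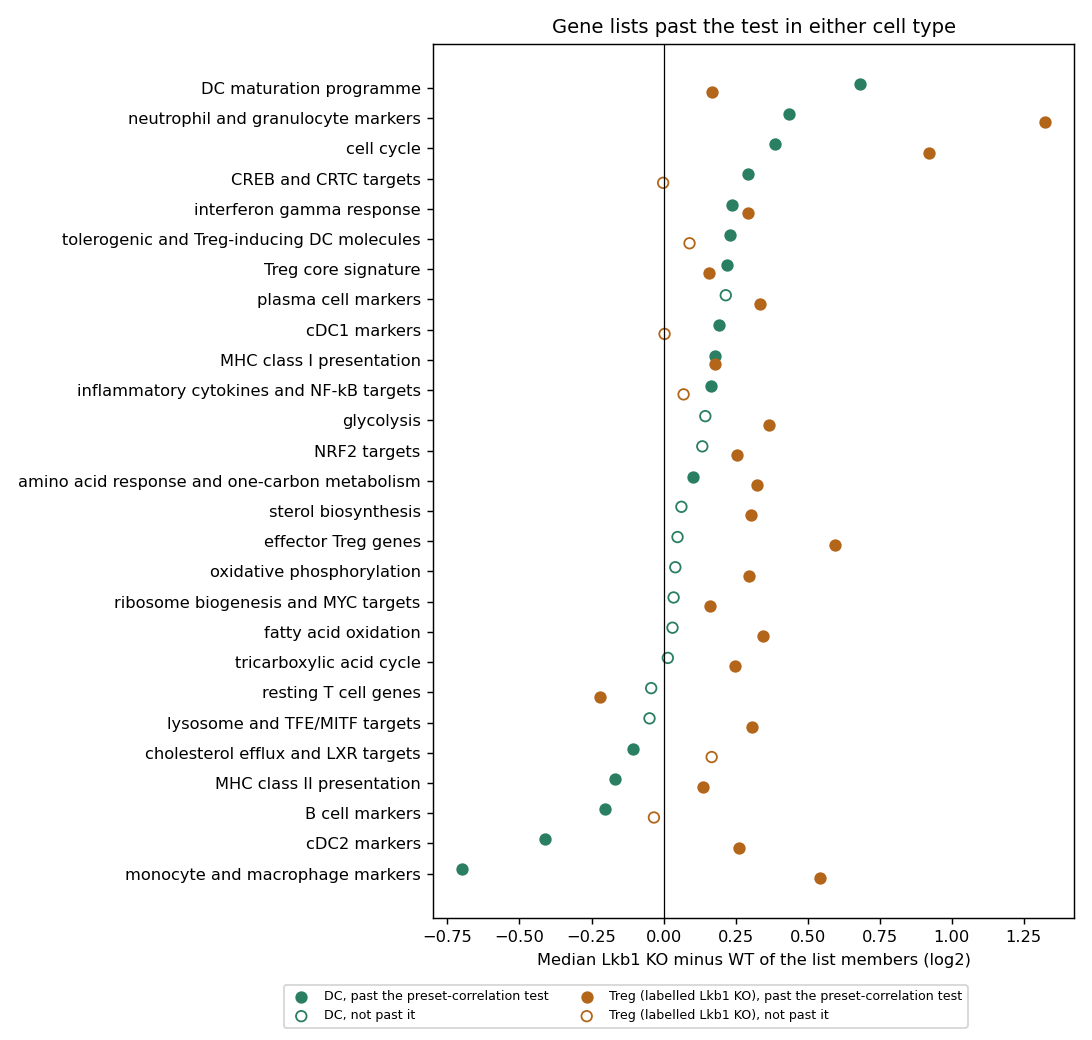
Median Lkb1 KO minus WT difference (log2) of the members of each gene list that passed the preset-correlation camera test in DCs or Tregs. Filled points passed and open points did not; with an estimated correlation 0 lists passed in either cell type, and Stk11 was not lower in the Treg arrays labelled Lkb1 KO.

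Groups did not overlap in 6044 of all 22180 genes (27.2%), which chance gives for 5.71% of genes. Of the 3155 Treg genes called, 150 differed at least 2-fold. Camera called 21 of 43 lists, 20 upward and 1 downward, but with an estimated correlation 0 passed (10 had an unadjusted p under 0.05), while fry kept 18 of the 21, all but MHC class II presentation (0.0693), interferon gamma response (0.0693) and macrophage markers (0.0764). Fry called 26 lists in all. Those that camera did not call were hypoxia targets (fry adjusted p = 0.00307), LKB1 and AMPK-related kinases (0.0127), tolerogenic molecules (0.015) and fatty acid synthesis (0.0172), all upward. T cell receptor response genes (0.0172), T cell markers (0.0247) and p53 targets (0.0251) were upward too, and stromal and endothelial markers (0.0179) downward. The number of genes fell to 1408, 1621 and 1502 when Lkb1 KO Treg 1, 2 or 3 was left out, and to 1770 without WT Treg 1 and Lkb1 KO Treg 1 together, a fit chosen after the data were seen. Medians over all clusters were 4.85 to 4.88 in WT Tregs and 4.70 to 4.74 in arrays labelled Lkb1 KO, so centring moves the median change of the genes tested from −0.003 to 0.136 and quantile normalization again to 0.0715. Centred that way, 5475 genes passed and 93.4% were higher, against 72.1% as given above; with every cluster tested, 5250 clusters passed and 44.3% were higher.

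The effect of the genotype label differed between DCs and Tregs for 2115 genes, 806 with a more positive and 1309 with a more negative value in DCs, while Stk11 was lower in knockout DCs alone. Mmp25 had the largest positive difference at 3.45 (SE 0.18; interaction adjusted p = 4.98e-09), as it changed by 3.96 in DCs and 0.51 in Tregs. Ramp3 (3.23), the semaphorin receptor gene Nrp2 (3.06), Flrt3 (2.88) and Nr4a2 (2.85) followed, and none of these 4 passed in Tregs. Slc40a1 had the largest negative difference at −3.85 (SE 0.56; interaction adjusted p = 2.76e-04), with −2.08 in DCs and 1.77 in Tregs. The chemokine receptor gene Ccr3 differed by −3.53, with −2.01 in DCs and 1.52 in Tregs. Atp6v0d2 (−3.00) rose in Tregs and was at −0.08 in DCs, whereas Mrc1 (−2.92) and the prostaglandin dehydrogenase gene Hpgd (−2.72) fell in DCs and did not pass in Tregs. The Treg call of Slc40a1 ended under 8 alternatives, 6 of which left out 1 array. Centring each array moved the median interaction value from −0.01 to −0.17. It gave 4061 genes, 11.8% of them positive against 38.1% as given above, and every cluster tested gave 3312 clusters, 60.4% positive; without Lkb1 KO Treg 1 the number was 1340.

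Genes called in both cell types numbered 378, of which 267 changed in the same direction and 111 in opposite directions. Il1r2 rose by 3.18 in DCs and 2.53 in Tregs, Ltf by 1.48 and 2.07, and Ngp by 1.46 and 2.22. Slc40a1 and Ccr3 fell in DCs and rose in Tregs, as did Axl, a receptor tyrosine kinase gene, from 8.79 to 7.42 in DCs and from 7.54 to 8.64 in Tregs. Genes higher in both were 233, where 84.1 would be shared by independent lists of the same sizes (odds ratio 3.76, 95% interval 3.19 to 4.41; Fisher's exact p = 4.30e-50, adjusted over 4 tests 1.72e-49). Of these 233, 9 were granulocyte markers, 8 cell cycle genes and 8 DC maturation genes. Genes lower in both were 34 against 24.8 (Fisher's exact p = 0.0611, adjusted 0.122). Those higher in DCs and lower in Tregs were 38 against 32.6 (Fisher's exact p = 0.316, adjusted 0.316), and those lower in DCs and higher in Tregs 73 against 64.1 (Fisher's exact p = 0.229, adjusted 0.305). The comparisons share no control arrays, but Fisher's test takes DC and Treg arrays as independent, while those of the same genotype and number tended to deviate together (r from 0.00716 to 0.206 over all genes). Fisher's test also takes genes as independent of each other. In Tregs the estimated correlation was 0.80 for cell cycle genes and 0.57 for granulocyte markers. The Fisher p-values and interval may thus overstate the precision of the overlap. Stk11 was not lower in the Treg arrays labelled Lkb1 KO. The 267 became 165 with every cluster tested, 6 with a required 2-fold change, and 144, 149 or 164 without Lkb1 KO Treg 1, 2 or 3.

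**Figure D5:**
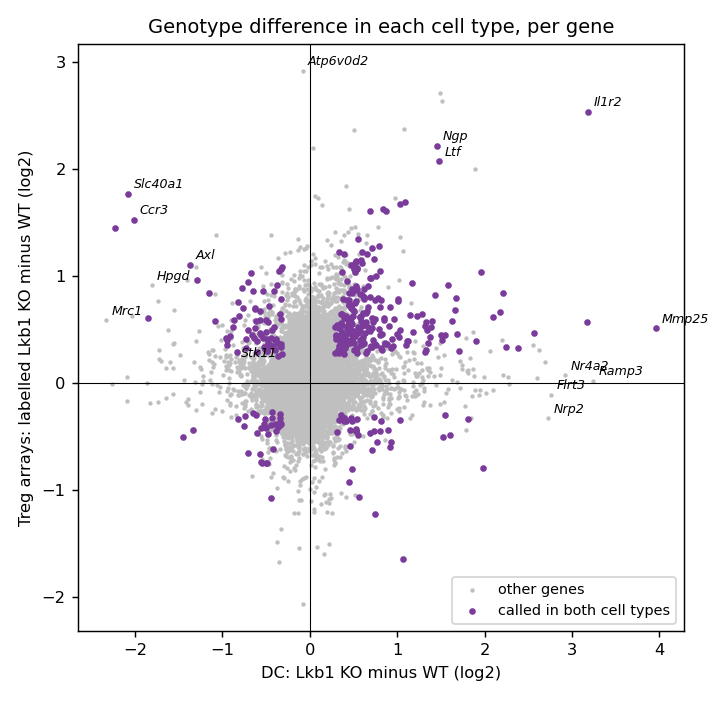
Difference with the Lkb1 genotype label in DCs (x axis, log2) against that in Tregs (y axis, log2) for each gene, with genes called in both cell types in purple. Il1r2 lies at 3.18 and 2.53, Slc40a1 at −2.08 and 1.77, and Stk11 at −0.85 and 0.19.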

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

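The splits within cell types were planned, whereas those that kept array numbers together and the tests on Stk11, on granulocyte genes and on clusters without a gene name were chosen after those results were seen.

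The real division of the arrays gave more genes than any other tried for the comparisons and the interaction. It did not give the most lists for the comparisons. With 35 splits the smallest share possible is 1 of 35, so chance is made unlikely but not excluded. Other splits also hold the real difference as spread within their groups, which lowers their counts. Of 35 splits of the DC arrays, 1, the real one, gave as many as 1445 genes, and the highest other gave 0. Of 35 splits of the Treg arrays, 1 gave as many as 3155 genes, and the highest other gave 587. That other split set WT Treg 2, 3 and 4 against WT Treg 1 and the 3 arrays labelled Lkb1 KO. Of 100 splits drawn within the cell types, 1 gave as many as 2115 genes with a different effect (highest other 1199). With DC and Treg arrays of the same genotype and number kept together, 1 of 35 splits gave as many (highest other 16). For the 267 genes shared in the same direction the splits decide nothing: 1 of 100 gave as many (highest other 0), but other divisions of the DC arrays called 0 genes, so an overlap was not possible there. For lists, 3 of 35 splits of the DC arrays gave at least 16 (highest other 17), and 6 of 35 splits of the Treg arrays gave at least 21 (highest other 24).

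Stk11 was not lower in the Treg arrays labelled Lkb1 KO (0.19, adjusted p = 0.129), unlike in knockout DCs. A probe set outside the deleted part is argued against by its change of −0.85 in knockout DCs (95% interval −1.05 to −0.65). An exchange of arrays between the WT and knockout Treg groups is argued against by the range of Stk11 over the 7 Treg arrays, 0.317, below the 0.654 that bounds the size of the DC fall. Tregs from animals in which the gene was deleted in other cells, and an outside sample under a wrong label, stay open. The labels do not say which cells carried the deletion, so neither was tested.

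Granulocyte genes were higher in knockout DCs and in the Treg arrays labelled Lkb1 KO, and RNA from granulocytes or their precursors in the sorted cells may account for members other than Il1r2 and Mmp9. Called members deviated together from their group means, with a median pairwise correlation of 0.804 over 8 members in DCs and 0.740 over 15 members in Tregs, where the 95th percentile of matched random lists was 0.230 and 0.124. These members were chosen by their calls in the same data. Other lists correlate as highly, with an estimated correlation of 0.80 for cell cycle genes in Tregs. The correlation thus cannot separate RNA of other cells from regulation within the sorted cells. The abundant S100a8 rose from 7.88 to 8.75 in DCs and from 7.62 to 9.23 in Tregs, where arrays overlapped, and S100a9 from 7.28 to 8.11 and from 7.09 to 8.71 (genes picked after their values were seen). The DC sort removed TCRβ, CD19 and CD49b positive cells and names no granulocyte marker, and the Treg sort required CD4 and CD25; 2 of the 22 members stand in another list, and 13 in WT DCs and 15 in WT Tregs were above the median gene. For Il1r2 in knockout DCs that source is argued against, since its SD over those arrays was 0.0321 times the median SD of the other called members (0.0122 against 0.380) and its rise of 3.18 exceeded their largest rise of 1.48, while a change of the sorted cells with the genotype stays open for all members, untested.

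Clusters outside the gene table, which the comparisons leave out, held signal differences: 182 of 16004 passed in DCs (127 higher, 55 lower) and 2610 in Tregs (414 higher, 2196 lower). A scaling factor per array is argued against as the cause in Tregs, because the gap between protein-coding and unnamed medians was 0.303 larger in arrays labelled Lkb1 KO, with their smallest gap (0.812) above the largest WT gap (0.660). A trend with signal level is argued against too: the median change of protein-coding genes matched on level was −0.00691, against −0.14 for the unnamed clusters, and lay 0.129 above it in the draw where they differed least. A lower share of nuclear or unspliced RNA may contribute: 8 nuclear-retained RNAs had a median change of −0.193, at the 0.86th percentile of random lists matched on level, and 4 of 8 passed, all lower: Malat1 (−0.48), Neat1 (−0.65), Xist (−0.34) and Airn (−0.72). Meg3 (−0.0000143), Firre (−0.05), Miat (0.14) and Rian (0.16) did not pass. Whether that share was lower, and whether through the cells or the preparation of RNA, stays open, and Stk11 was not lower in these arrays.

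Effects differed between cell types by the interaction test for 2115 genes, and among named genes the DC effect minus the Treg effect was as follows: Mmp25 3.45, Ramp3 3.23, Nrp2 3.06, Flrt3 2.88, Nr4a2 2.85, Slc40a1 −3.85, Ccr3 −3.53, Atp6v0d2 −3.00, Mrc1 −2.92, Hpgd −2.72 and Stk11 −1.05. Of 119 groups of 4 arrays examined for an array far from the others, 5 had one, and chance gives about 1 in 20. Timd4 was 8.28 in Lkb1 KO DC 3 against 7.90 to 7.93 in the others of its group. Cyp4f37 was 5.50 in Lkb1 KO DC 3 against 6.42 to 6.58. Cd5l was 4.61 in Lkb1 KO DC 4 against 4.23 to 4.26. The mean of tolerogenic and Treg-inducing DC molecules was 6.54 in WT DC 1 against 6.49 to 6.50, and that of cholesterol efflux and LXR targets 7.14 in Lkb1 KO DC 1 against 6.96 to 6.98.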

How the results depend on the processing

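Alternatives were planned, except the fit without WT Treg 1 and Lkb1 KO Treg 1 together, the fit on protein-coding genes and a block shared between cell types, all chosen after seeing the data. Centring each array on its median gave 5475 Treg genes (93.4% higher), 4061 interaction genes (11.8% positive) and 0.33 for Stk11 in Tregs, now past the threshold. Every cluster tested gave 5250 Treg clusters (44.3% higher; 2610 outside the gene table), 3312 interaction clusters, 34 Treg lists and an overlap of 165. A required 2-fold change gave 242 DC genes, 150 Treg genes, 424 interaction genes and an overlap of 6, fewer by construction. Dim genes left out gave 13 Treg lists, and an estimated correlation 0 lists in DCs and 0 in Tregs. The added fit without both arrays gave 1770 Treg genes. The lower median of unnamed clusters in Treg arrays labelled Lkb1 KO enters the centring and the count with every cluster; for the other values the cause was not tested.

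With 1 array left out in turn, DC genes ranged from 1059 to 1296 and DC lists from 13 to 20. Treg genes ranged from 1408 to 3338 and Treg lists from 19 to 25. Interaction genes ranged from 1340 to 2885 and the overlap from 144 to 284. Stk11 ranged from −0.90 to −0.78 in DCs and from 0.17 to 0.22 in Tregs.

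With a replicate block the values were 1470 DC genes, 2271 Treg genes, 1816 interaction genes, 17 DC lists, 24 Treg lists, an overlap of 234, and Stk11 at −0.85 and 0.21. Among the calls of the main fits, 1281 of 1445 DC genes and 2043 of 3155 Treg genes passed with that block. Residual correlations between WT and KO arrays of the same number were −0.04 to 0.25 in DCs and −0.04 to 0.14 in Tregs. Between DC and Treg arrays of the same genotype and number they were 0.00716 to 0.206, over 0.1 in 4 of 7 pairs, and 6 of 7 Treg arrays correlated best with the DC array of their own number, a hint of a shared source from the data and not from the labels. Erythroid marker means were lowest in array 2 and highest in array 3 of all 4 groups. That order holds across genotypes, whereas the main fits take WT and KO arrays as unpaired. A replicate block shared by DC and Treg arrays of the same genotype and number gave 2160 interaction genes.

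Named genes kept their direction and side of the threshold in 2060 of 2165 values in DCs, 2032 of 2285 in Tregs and 251 of 251 for the interaction. Counted by gene, 103 of 128 in DCs, 83 of 143 in Tregs and 11 of 11 for the interaction did so in every setting. The direction turned in 1 value: Rpl3 in Tregs with the mean of all clusters of a gene was −0.16 (adjusted p = 0.221). With 3 or 4 arrays per group small changes can be missed: of simulated changes of 0.5 the fit recovered 32% in DCs and 50% in Tregs. The simulation called 130 and 150 genes, against 1445 and 3155 in the real data. More calls ease the adjusted threshold, so these shares do not carry over directly to the real data.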

Other observations

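The list test of the interaction was added after the data were seen. DC maturation genes had a more positive effect in DCs than in Tregs: 20 of 36 members passed upward and 0 downward, or 27 and 1 adjusted over the list alone (camera adjusted p = 1.38e-18; adjusted p = 0.0244 with an estimated correlation). It was the 1 list of 43 that passed with an estimated correlation, whereas 15 passed at the preset correlation. Monocyte and macrophage markers had a more negative effect in DCs, with 1 of 28 members past the threshold upward and 19 downward, or 1 and 24 adjusted over the list alone (camera adjusted p = 5.95e-14; adjusted p = 0.170 with an estimated correlation). Effector Treg genes had 1 and 16 of 33, or 2 and 20 adjusted over the list alone (camera adjusted p = 1.17e-09; adjusted p = 0.181 with an estimated correlation). Lysosome and TFE/MITF targets had 0 and 12 of 34, or 1 and 18 adjusted over the list alone (camera adjusted p = 1.09e-08; adjusted p = 0.152 with an estimated correlation). Oxidative phosphorylation had 0 and 2 of 53, or 0 and 0 adjusted over the list alone (camera adjusted p = 5.84e-06; adjusted p = 0.405 with an estimated correlation). Tricarboxylic acid cycle genes had 0 and 6 of 19, or 0 and 11 adjusted over the list alone (camera adjusted p = 2.80e-06; adjusted p = 0.230 with an estimated correlation).

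Further lists with a more negative effect in DCs follow. Markers of cDC2s had 1 and 16 of 27, or 1 and 20 adjusted over the list alone (camera adjusted p = 2.08e-10; adjusted p = 0.152 with an estimated correlation). MHC class II presentation genes had 0 and 6 of 18, or 0 and 6 adjusted over the list alone (camera adjusted p = 3.18e-05; adjusted p = 0.257 with an estimated correlation). Granulocyte markers had 1 and 3 of 22, or 1 and 9 adjusted over the list alone (camera adjusted p = 1.03e-04; adjusted p = 0.405 with an estimated correlation). Cell cycle genes had 0 and 2 of 38, or 0 and 1 adjusted over the list alone (camera adjusted p = 3.22e-08; adjusted p = 0.495 with an estimated correlation). Fatty acid oxidation had 0 and 6 of 23, or 0 and 8 adjusted over the list alone (camera adjusted p = 0.00957; adjusted p = 0.360 with an estimated correlation). Glycolysis had 1 and 4 of 21, or 1 and 5 adjusted over the list alone (camera adjusted p = 0.0288; adjusted p = 0.405 with an estimated correlation). LXR targets had 0 and 4 of 9, or 0 and 4 adjusted over the list alone (camera adjusted p = 0.0107; adjusted p = 0.299 with an estimated correlation).

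Another 2 lists had a more positive effect in DCs. Resting T cell genes had 6 and 0 of 19, or 8 and 1 adjusted over the list alone (camera adjusted p = 2.52e-04; adjusted p = 0.172 with an estimated correlation). CREB and CRTC targets had 6 and 3 of 18, or 7 and 3 adjusted over the list alone (camera adjusted p = 0.00243; adjusted p = 0.311 with an estimated correlation). With fry 13 of the 15 were kept, all but cell cycle genes (0.107) and granulocyte markers (0.0534). Fry also called plasmacytoid DC markers (adjusted p = 0.0482) and T cell receptor response genes (0.0336) as more positive in DCs. It called amino acid response genes (0.0188) and B cell markers (0.00533) as more negative. Stk11 was not lower in the Treg arrays labelled Lkb1 KO.

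Calls in the Treg arrays labelled Lkb1 KO are given here by class of gene, without a test between classes. Of 17594 protein-coding genes outside the receptor families 2210 were higher and 602 lower. Of 1921 long non-coding RNA genes 13 were higher and 105 lower, of 472 microRNA genes 3 and 81, and of 1394 olfactory and vomeronasal receptor genes 3 and 40. In DCs the same classes had 767 and 585, 31 and 21, 4 and 5, and 6 and 5. Median changes in Tregs, beside a median of −0.003 over all genes tested, were 0.02, −0.07, −0.11 and −0.07. Centring moves all genes of an array alike and brings the median over all genes to 0.136. It therefore turns the 3 negative medians positive, while their distance below the median over all genes stays. Quantile normalization again brought that median to 0.0715, and the classes were not counted there.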
